A study of Homo sapiens with 6 samples.

How the data were processed

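RNA of 2 human Ewing tumor cell lines, A673 and SK-N-MC, was measured on 6 Affymetrix Human Gene ST arrays, 1 column of values per array. Each line had 1 control array and 2 arrays of cells that had received a short interfering RNA (siRNA) against STEAP1. The control siRNA is not named in the labels used here, the A673 control carries the number 2 and the SK-N-MC control none, and whether both lines got the same control siRNA is not stated. The siRNAs against STEAP1 carry the numbers 2 and 3 in the labels, and the same number stands for the same siRNA in both lines. Per the labels' protocols, siRNA was used at 5 nM for 48 h, cells were taken at 80% confluency and 200 ng of RNA entered the labelling. The labels do not say whether the arrays of one line came from separate cultures, so p-values measure only the spread between these arrays, and both siRNAs were treated as replicates of silencing. With 1 control array per line, no spread between control arrays could be estimated, and the number of arrays limits the precision.

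The deposited values are intensities on a linear scale. The authors made them with RMA in Affymetrix Expression Console 1.1, per the submitters' processing notes, and the step that took the summaries back to a linear scale is not given in the sources used here. No further normalization was applied in the main fit, and log2 of each intensity was taken. Column medians lay between 6.01 and 6.48, upper quartiles between 27.2 and 29.4 and maxima between 6795 and 7789 intensity units. No detection calls were used, so low values have no stated floor.

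The value table holds 33297 probe sets. The platform annotation used here lists 21214 of them, of which 19460 carry 1 gene symbol and 1754 carry several, and the other 12083 are unnamed here. Symbols were updated by gene identifier through a RefSeq table of assembly GRCh38.p14, used only for names. It matched 19429 of the 19460 probe sets, and the other 31 kept the annotation's symbol. Of the probe sets of one gene, the one with the highest mean over the 6 arrays was used, which left 18417 genes, 769 of them with more than 1 probe set. No gene was named from a probe set with several symbols.

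All tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05). Silencing across both lines and the difference between the lines came from a fit with a cell line term and a silencing term (3 residual degrees of freedom). The response within each line and the difference of the responses came from a fit of 4 group means (2 residual degrees of freedom). The difference between the siRNAs came from a fit with a cell line term and a term for each siRNA (2 residual degrees of freedom). For 25 gene lists, camera compared the members with all other genes at a preset correlation of 0.01, with an estimated correlation and a rank version as alternatives, and STEAP1 was kept out of every list. The estimated correlation rests on only 2 or 3 residual degrees of freedom. It called 0 lists in every comparison, also between the lines, so a missed call under it says little. Genes that moved at least 1.5-fold the same way in all 4 siRNA arrays were counted and set against 10000 shuffles of the genes of one line. Responses were compared between arrays by Pearson correlation across genes, which are not independent replicates.

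The comparisons, the lists and the rule for naming genes were fixed before the data were examined. Across lines the rule names STEAP1 and, in each direction, the 12 genes past the threshold with the largest change. Where fewer pass, it names those whose smallest change over the 4 siRNA arrays, all of 1 sign, is largest, as values and not as calls. Within lines, for their difference and between siRNAs, genes past the threshold are named, or else the 3 largest changes in each direction. Between lines the 12 largest calls in each direction are named. The rule also names STEAP family genes, and EWSR1, FLI1, GAPDH, ACTB and B2M. Of each list it names members with the smallest p in the fit with a cell line term and a silencing term. List members named for a small p in another fit, such as MKI67 between the siRNAs, fall outside the fixed rule. Members called only over their own list were named after their values were seen.

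The fits were tested on simulated data for 18417 genes with known changes. Changes were planted only in genes with a mean log2 of at least 4, in 100 genes of each size at once. Noise was normal and independent between genes, and changes across lines had the same size in both lines. Shares for dim genes, fewer changes or unlike lines may be lower. In the fit across lines, 64.1% of genes changed 2-fold and 95.2% of genes changed 4-fold were called. Within A673 these shares were 1.2% and 64.9%, within SK-N-MC 1.3% and 66.6%, and for the difference of the responses 0% at both sizes. Between siRNAs they were 28.3% and 83.5%, and between lines 72% and 95.6%. Simulated lists of 43 genes shifted across lines by -0.50 on the log2 scale were called in 20 of 20 draws, and 0 of 480 unshifted lists were called. Members of these lists were random genes that varied independently, so false calls of lists whose members move together were not tested.

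Alternatives were an intensity trend in eBayes, a filter at a mean log2 of 6, the mean of a gene's probe sets, a second quantile normalization, median centring, each array left out, no cell line term, the siRNA number as a block, every probe set of the table and each siRNA alone. A milder filter at a mean log2 of 4 and a correlation without the interferon list and STEAP1 were added after the data had been seen, because only 2391 genes pass the planned filter while 7413 pass the milder one. Genome coordinates were not used here.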

Results

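Gene expression was measured in A673 and SK-N-MC, 2 established Ewing tumor cell lines, after siRNA against STEAP1, a transmembrane metalloreductase family member. Each line gave 1 control array, 1 array with siRNA 2 and 1 array with siRNA 3, and 18417 genes were compared. Values are log2 of the deposited array intensity, and errors of differences are standard errors (SE) from the limma fit. Arrays of the same line correlated across genes at 0.986 to 0.993, and arrays of different lines at 0.946 to 0.949.

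The first comparison asks whether the target transcript was lowered. STEAP1 was at 7.15 in the SK-N-MC control array, 4.17 with siRNA 2 and 4.73 with siRNA 3. In A673 it was at 6.23 in the control array, 4.53 with siRNA 2 and 4.59 with siRNA 3. This left 12.7% and 18.7% of the control level in SK-N-MC, and 30.8% and 32.1% in A673. STEAP1 had the smallest p of all genes across both lines (log2 difference -2.18, SE 0.24, lower in 4 of 4 siRNA arrays), with an adjusted p of 0.293. The difference did not pass the threshold over 18417 genes.

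**Figure D1:**
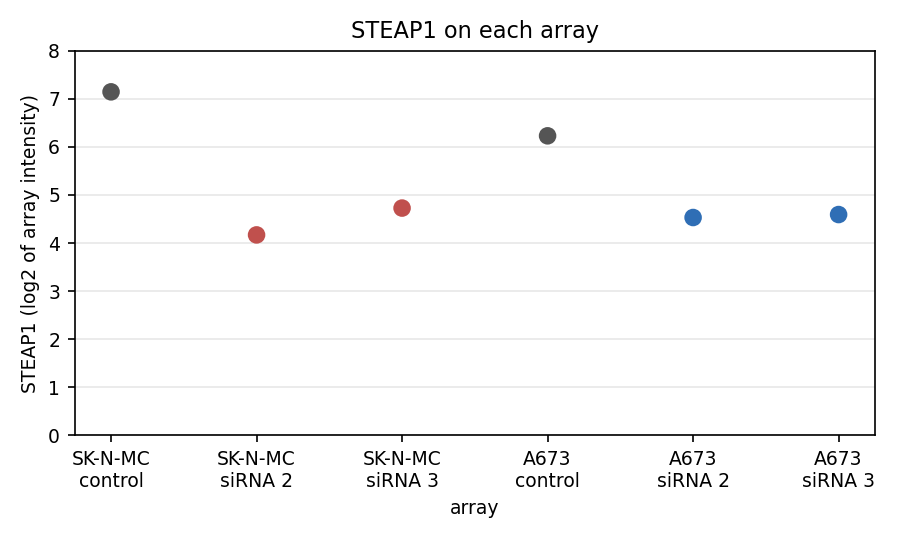
STEAP1 on each of the 6 arrays, as log2 of array intensity on the vertical axis, with 1 point per array. Control arrays (grey) lie at 7.15 and 6.23, and the 4 siRNA arrays lie between 4.17 and 4.73.

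The other STEAP family genes showed no call. STEAP1B differed by -0.34 (SE 0.17) across lines and was lower in 4 of 4 siRNA arrays, with an adjusted p of 0.989. STEAP3 was higher by 0.30 and 0.20 in the SK-N-MC siRNA arrays and lower in A673, at -0.38 and -0.62. STEAP2 (-0.01, SE 0.16) and STEAP4 (-0.04, SE 0.14) differed by less than their SE, and the sign of STEAP2 was reversed after a second quantile normalization, at 0.01. The fusion partners EWSR1 and FLI1 differed by at most 0.12 from their control array in any siRNA array, and GAPDH by at most -0.14.

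Across both lines the next comparison asks which genes followed the silencing of STEAP1 in both backgrounds. Among the lower values, PSMB9 differed by -1.32 (SE 0.30), APOL2 by -0.83 (SE 0.15) and IFI30 by -0.75 (SE 0.13). Each was lower in 4 of 4 siRNA arrays. The value of PSMB9 came mainly from SK-N-MC: it stood at -2.07 without the A673 control array and -0.57 without the SK-N-MC control array. The collagenase gene MMP1 lay at 9.91 in the A673 control array, 8.14 with siRNA 2 and 9.36 with siRNA 3, and at 2.69 to 1.98 in SK-N-MC, where it was dim (log2 difference -0.89, SE 0.30, -0.58 without the A673 siRNA 2 array). No gene passed the threshold: limma called 0 genes higher and 0 lower, and 852 genes had an unadjusted p under 0.05 where 921 are expected by chance. The same fit recovered 64.1% of simulated 2-fold changes, planted in genes with a mean log2 of at least 4 and alike in both lines. STEAP1 itself, lower in 4 of 4 siRNA arrays, was not called, so this share may be too high for real changes.

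The remaining lower genes of the naming rule were AGPAT4, TMEM119, ZNF594, PFN4, PTPN22, CRYGS, GRAP and GM2A, with differences from -0.97 for ZNF594 to -0.61 for CRYGS. The higher genes were ZNF626 (1.18, SE 0.23), EOLA1-DT (1.09, SE 0.20, 0.69 without the SK-N-MC control array), DNM1P46 (0.98, SE 0.16), SNORD13P2 (0.75, SE 0.11), KIAA1671, MEIS3, GNRH2, TMEM70, LILRP2, MAGEL2, S1PR2 and GPR153, the last at 0.52. All of these had adjusted p-values of at least 0.882. The other probe sets of ZNF626 (0.15) and DNM1P46 (0.24 and -0.04) differed by less. TMEM70, the brightest of the higher genes, lay at 5.33 and 4.13 in the control arrays, and MAGEL2 at 1.34 and 1.68.

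At least 1.5-fold in all 4 siRNA arrays, 4 genes were higher (EOLA1-DT, MEIS3, SNORD13P2 and ZNF626) and 2 were lower (IFI30 and STEAP1). Shuffling the genes of one line gave a mean of 0.122 higher genes and 0.677 lower genes. As many higher genes came up with a one-sided permutation p of 0.0001, the smallest that 10000 shuffles can give, and as many lower genes with p = 0.145. None of the 4 higher genes had a mean log2 of 4 or more. The shuffle exchanges genes of all levels, so dim genes that vary widely in both lines can exceed it without an effect of silencing. The 2 siRNA arrays of a line also share 1 control array, so this p does not show a shared response.

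Among genes of redox, signalling and matrix lists, single members had the same sign in all 4 siRNA arrays without passing the threshold. GLRX differed by -0.42 (SE 0.11), EGR1 by -0.49 (SE 0.12), TIMP1 by -0.51 (SE 0.16), TGFBR2 by -0.45 (SE 0.14), ACTA2 by -0.90 (SE 0.22) and PPP1R1A, a target of the EWSR1-FLI1 fusion, by -0.41 (SE 0.12). HK2 differed by 0.69 (SE 0.17) and ITGB1 by 0.32 (SE 0.12). With the control array of one line left out, the fit gives the response of the other line alone. For SK-N-MC this was -1.36 for ACTA2, -0.73 for TIMP1, -0.20 for TGFBR2 and 1.05 for HK2. For A673 it was -0.43, -0.30, -0.70 and 0.33 in the same order. Whether the lines differ is not settled: the direct test of that difference called 0 genes, and it recovered 0% of simulated changes. GSR, at -0.26 (SE 0.14), was lower in 3 of 4 siRNA arrays. These genes had an adjusted p of 0.989.

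Of the 25 gene lists, 1 was called across both lines. The interferon response list, with 43 members measured, had a mean log2 difference of -0.92 and a median of -0.91, and 42 of its 43 members were lower (camera adjusted p = 5.87e-20). It was not called with an estimated correlation (adjusted p = 0.949 with an estimated correlation), a version that called 0 lists in every comparison and so can hardly decide. Over all genes or adjusted over the list alone, 0 members were called. The value came from SK-N-MC: without the SK-N-MC control array the mean was -0.05 and camera gave an adjusted p of 0.614. The other 24 lists had means between -0.15 and 0.05 and camera adjusted p-values from 0.119 to 0.911. The mesenchymal and TGF-beta list stood next, at a mean of -0.15 over 21 members. B2M differed by -0.59 (SE 0.23) and was lower in 4 of 4 siRNA arrays, at -0.88 without the A673 control array and -0.30 without the SK-N-MC control array.

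**Figure D2:**
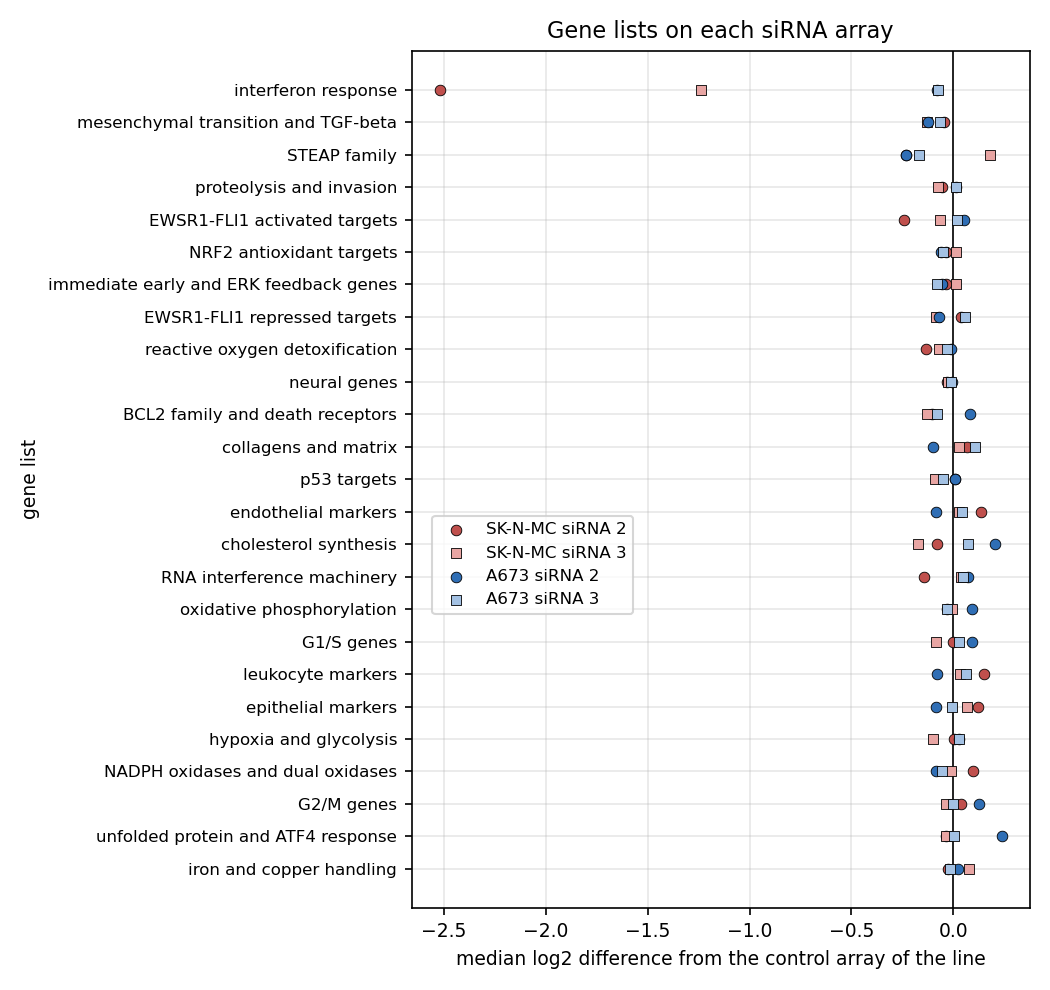
Median log2 difference of each of the 25 gene lists from the control array of its line, on the horizontal axis, with 1 point per siRNA array (red SK-N-MC, blue A673, circles siRNA 2, squares siRNA 3). The interferon response list lies at -2.52 and -1.24 in SK-N-MC and at -0.08 and -0.07 in A673, while every other list lies between -0.24 and 0.24.

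Within SK-N-MC, interferon-stimulated genes were lower in both siRNA arrays. XAF1 was the only gene called: it fell by 2.59 (SE 0.18), from 5.07 in the control array to 2.43 and 2.52 (adjusted p = 0.0466). OAS2 differed by -2.95 (SE 0.27), HERC5 by -2.78 (SE 0.29), PSMB9 by -2.07 (SE 0.22) and IRF1 by -1.97 (SE 0.16), with adjusted p-values of 0.0681 to 0.0891. STEAP1 differed by -2.70 (SE 0.24, adjusted p = 0.0681), and passed the threshold under 3 alternatives for the processing and without either SK-N-MC siRNA array (adjusted p 0.00152 to 0.0402). In both siRNA arrays XAF1, OAS2, HERC5 and IRF1 lay below the median of the array, where no detection calls were used, so the sizes of their differences are uncertain. The spread comes from 2 residual degrees of freedom, and without either A673 siRNA array XAF1 had an adjusted p of 0.712. limma called 0 genes higher and 1 lower, and 943 had an unadjusted p under 0.05. With 1 SK-N-MC siRNA array left out, 8 genes were lower without siRNA 2, and 60 were lower and 1 higher without siRNA 3. Each SK-N-MC group then holds 1 array, the spread comes from the A673 siRNA arrays alone, and SK-N-MC arrays are assumed to vary like them.

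The interferon response list as a whole had a mean of -1.79 and a median of -1.82 in SK-N-MC (camera adjusted p = 8.59e-46, adjusted p = 0.856 with an estimated correlation). Of its 43 members, 33 were called lower adjusted over the list alone and 1 over all genes. The 2 siRNA arrays differed: the median was -2.52 with siRNA 2 (42 members lower) and -1.24 with siRNA 3 (41 members lower). MX1 lay at 7.75 in the control array, 2.65 with siRNA 2 and 5.57 with siRNA 3, CXCL10 at 6.73, 1.53 and 4.75, and IFIT1 at 8.39, 3.59 and 7.03. Only 1 control array sets this comparison.

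**Figure D3:**
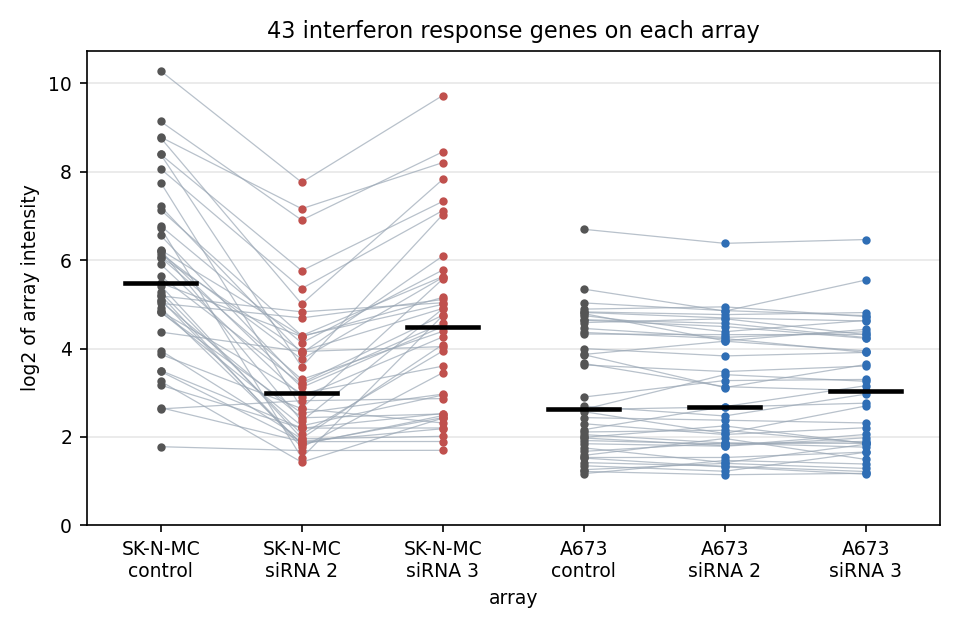
The 43 measured members of the interferon response list on each array, as log2 of array intensity on the vertical axis, with lines joining each gene within a line and black bars for medians. The median is 5.48 in the SK-N-MC control array, 2.98 with siRNA 2 and 4.50 with siRNA 3, and 2.62, 2.69 and 3.05 in A673.

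Other members of fixed lists were called in SK-N-MC when adjusted over the list alone, 2 genes in all, and neither over all genes. ACTA2 differed by -1.36 (SE 0.21, adjusted p over all genes 0.320) and HK2 by 1.05 (SE 0.18, adjusted p over all genes 0.369). The largest differences on the higher side were EOLA1-DT (1.49, SE 0.22), DNM1P46 (1.27, SE 0.19) and TYW1B (1.23, SE 0.43, 0.74 without siRNA 2), none of them called. With ranks in place of values, camera also called the EWSR1-FLI1 activated targets in SK-N-MC (mean -0.16, 20 of 27 lower, adjusted p = 0.0431) and in the difference of the responses (mean 0.18, adjusted p = 0.0451). Camera on values called neither (adjusted p of at least 0.0920), and with an estimated correlation adjusted p was 0.856 and 0.751.

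Within A673, STEAP1 had the largest difference of all genes on the lower side, at -1.67 (SE 0.24). LYRM9 (-1.35, SE 0.17) and OR1F2P (-1.34, SE 0.21) followed, and H2AC8 (1.26, SE 0.19), FMN1 (1.25, SE 0.39) and ZNF626 (1.21, SE 0.35) led the higher side. FMN1 stood at 0.72 without siRNA 3 and 1.79 without siRNA 2, and across lines its other probe set differed by 0.022 beside 0.14. LYRM9, OR1F2P, H2AC8 and FMN1 lay below 3 in the A673 control array, and histone genes such as H2AC8 have near-identical copies, so their values are uncertain. limma called 0 genes (lowest adjusted p 1.00), and 617 had an unadjusted p under 0.05. No list was called: the interferon response list had a mean of -0.05 (camera adjusted p = 0.614). Of simulated 2-fold changes this fit recovered 1.2%.

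The response of A673 minus that of SK-N-MC was tested directly. The interferon response list differed by a mean of 1.74 and a median of 1.94, with 40 of 43 members on the positive side (camera adjusted p = 2.24e-32, adjusted p = 0.751 with an estimated correlation), and by 1.16 without the SK-N-MC siRNA 2 array. Of its members, 19 were called adjusted over the list alone and 0 over all genes. In the A673 control array the list median (2.62) was that of the whole array (2.62), so most members had little room to fall there. The 15 members at a log2 of 4 or more in that array had median responses of -0.16 in A673 and -1.54 in SK-N-MC. MX1 (3.68, SE 1.39), CXCL10 (3.53, SE 1.52) and IFIT1 (3.11, SE 1.65) had the largest positive differences, and stood at 2.22, 1.93 and 1.39 without the SK-N-MC siRNA 2 array. TYW1B (-2.18, SE 0.61), OR1F2P (-2.04, SE 0.29) and CSRP2 (-1.64, SE 0.31) had the largest negative ones. limma called 0 genes, with 711 at an unadjusted p under 0.05. Without the SK-N-MC siRNA 3 array 26 genes were called, 20 of them interferon list members, with a spread that comes from the A673 siRNA arrays alone.

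A further comparison asks how far the 2 siRNAs had different effects. With siRNA 2 against siRNA 3 in both lines, CAV1 (-0.94, SE 0.17), ITGAV (-0.74, SE 0.14), DICER1 (-0.71, SE 0.14), ADAM10 (-0.69, SE 0.15) and ITM2A (-0.68, SE 0.13) were lower. SESN2 (0.82, SE 0.14) and MTHFD2 (0.54, SE 0.14) were higher, and PSAT1 (-0.75, SE 0.15) was lower. These 8 genes were called adjusted over the list alone, and 0 genes were called over all genes, where 1229 had an unadjusted p under 0.05. CAV1 was lower than in the control array with siRNA 2 in both lines (-1.11 and -0.55) and close to it with siRNA 3 (0.09 and 0.12). The largest differences were RTRAF (0.96, SE 0.17), SLC25A15 (0.94, SE 0.19, 0.61 without SK-N-MC siRNA 2) and FRG1BP (0.94, SE 0.15) on the higher side, and IFIT1 (-1.97, SE 0.84), CXCL10 (-1.62, SE 0.93) and MX1 (-1.56, SE 0.91) on the lower. The last 3 rested on 1 array: without SK-N-MC siRNA 2 they stood at -0.084, 0.45 and 0.39.

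Camera called 4 lists between the siRNAs. Interferon response genes had a mean of -0.60 (adjusted p = 6.26e-06, adjusted p = 0.813 with an estimated correlation), and the mean was 0.26 without the SK-N-MC siRNA 2 array and -1.46 without the A673 siRNA 2 array. G2/M genes stood at 0.11 (adjusted p = 0.0218), with MKI67 at 0.61 (SE 0.14). G1/S genes stood at 0.10 and the unfolded protein and ATF4 list at 0.10 (both adjusted p = 0.0443). For these 3 lists, the value was adjusted p = 0.787 with an estimated correlation. Calls of these 3 lists were lost with single arrays left out, some with little change in the mean. G2/M genes lost theirs at means of 0.092 and 0.13 without the A673 siRNA 2 and siRNA 3 arrays and 0.095 without SK-N-MC siRNA 3 (adjusted p up to 0.348). G1/S genes lost theirs without any array except A673 siRNA 3. For these the mean stayed at 0.10 without either control array (adjusted p = 0.0539), was 0.083 without SK-N-MC siRNA 2 and 0.12 without A673 siRNA 2, and was 0.032 without SK-N-MC siRNA 3 (adjusted p = 0.577). Median centring left G1/S and unfolded protein genes at 0.11 (both adjusted p = 0.0504), and the latter also lost their call at 0.059 with a limit of 6 (0.109) and 0.088 with a limit of 4 (0.101). The mean of the unfolded protein and ATF4 list was unchanged without the control array of either line, which does not enter this difference, though its call was lost (adjusted p = 0.0520). The list stood at -0.06 and -0.01 without the A673 siRNA 2 and siRNA 3 arrays.

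Responses agreed little between the lines across all genes. The mean correlation of responses was 0.0663 for the same siRNA and 0.0247 for different siRNAs. The same-siRNA pairs gave 0.0232 for siRNA 2 and 0.109 for siRNA 3, and the different-siRNA pairs 0.0493 and 3.92e-05. The siRNA 2 pair thus lay below 1 of the different-siRNA pairs. Among 2391 genes with a mean log2 of at least 6 the means were 0.282 and 0.0789. There the same-siRNA pairs gave 0.260 and 0.305, and the different-siRNA pairs 0.141 and 0.0167. The siRNA 2 minus siRNA 3 difference, which uses no control array, correlated between the lines at 0.299 in these genes, at 0.193 in genes with a mean log2 of at least 4 and at 0.0663 in all genes. Within a line the 2 responses share a control array and correlated at 0.503 in SK-N-MC and 0.485 in A673, where 0.50 comes up with no effect at all. Their covariances were 0.0453 and 0.0285, beside 0.0388 in the simulation. The simulation used 1 spread for both lines. The log2 difference between the 2 siRNA arrays had a standard deviation of 0.307 in SK-N-MC and 0.246 in A673. The 0.0388 thus cannot show whether either covariance exceeds that of no effect in its own line.

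The cell lines themselves differed widely, with 2479 genes higher in A673 and 2096 higher in SK-N-MC, together 24.8% of genes. A673 had more MMP1 (115-fold), AKR1C3 (111-fold), CES1 (46.6-fold), TNFAIP6 (45.2-fold), DCC (38.5-fold), CSRP1 (33.9-fold), KCNE4 (31.8-fold) and OTX2 (30.2-fold). The histone genes H3C11 (197-fold), H2BC14 (79.5-fold), H1-5 (36.3-fold) and H1-1 (28.2-fold) were also higher, and near-identical copies make these and AKR1C3 uncertain. SK-N-MC had more CCND2 (log2 difference -5.52, SE 0.14), TFAP2B (-5.42, SE 0.16), TSHZ3, LCP1, LIN28B, CYP1B1, CDKN2A and MAPT (-3.65, SE 0.17), and the interferon-inducible IFI44L, IFI6, SAMD9 and BST2. Each of these 24 genes had an adjusted p of at most 9.08e-04. In the line with less, 12 of the 24 lay at or below the median of the array on all 3 arrays, and MMP1, OTX2, TFAP2B and CDKN2A on 2 of 3, so the sizes of these differences are uncertain. Without the control array of either line, 1330 genes were lower in A673.

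Lists of metabolic and stress genes were compared between the lines as well. Cholesterol synthesis genes were higher in A673 by a mean of 1.14 (15 of 18 called, all higher, with 15 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.79e-10, adjusted p = 0.399 with an estimated correlation), among them SC5D (2.48, SE 0.11) and DHCR7 (1.96, SE 0.12). Unfolded protein and ATF4 response genes were higher by 0.87 (adjusted p = 4.13e-09, adjusted p = 0.467 with an estimated correlation), with SLC7A5 at 2.86 (SE 0.11) and HYOU1 at 2.54 (SE 0.17). Interferon response genes were lower in A673 by a mean of -1.46 (adjusted p = 4.71e-07, adjusted p = 0.515 with an estimated correlation), although PARP14 was higher by 3.16 (SE 0.10). The mean of the interferon list was -0.88 without either control array and -1.96 without the SK-N-MC siRNA 2 array, and with a limit of 6, which 3 members pass, it was -3.08. G2/M genes were higher by 0.32 (adjusted p = 1.85e-04, adjusted p = 0.467 with an estimated correlation), with UBE2C at 1.23 and TOP2A at -1.21. None of these lists was called with an estimated correlation, which called 0 of the 25 lists in every comparison and so says little against them.

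Called with smaller margins between the lines were immediate early and ERK feedback genes (mean 0.61, adjusted p = 0.00302), proteolysis and invasion genes (0.40, adjusted p = 0.0278), NRF2 antioxidant targets (0.72, adjusted p = 0.0278) and hypoxia and glycolysis genes (0.47, adjusted p = 0.0430). None of the 4 lists was called with an estimated correlation (adjusted p = 0.399 to 0.467 with an estimated correlation). DUSP6 was higher in A673 by 4.18 (SE 0.18), SPRY2 by 1.29 (SE 0.10), ENO2 by 3.28 (SE 0.12) and HK1 by 2.62 (SE 0.20). Among genes with a mean log2 of at least 6, the immediate early list stood at -0.08, NRF2 targets at 0.24 and hypoxia genes at 0.22 (adjusted p = 0.462 for both). Other losses of a call came without a mean near 0. With the limit at 4 none of the 4 lists was called (adjusted p 0.151 to 0.452), at means of 0.68, 0.76, 0.56 and 0.46 in the order above. Median centring gave proteolysis genes 0.45 (adjusted p = 0.0510), NRF2 targets 0.77 and hypoxia genes 0.53 (both 0.0540). With ranks in place of values, NRF2 targets had an adjusted p of 0.0700 and hypoxia genes 0.116. Proteolysis genes stood at 0.34 (adjusted p = 0.0614) without the A673 siRNA 3 array. Hypoxia genes stood at 0.43 (0.0715) without the SK-N-MC siRNA 3 array and 0.45 (0.0661) without the A673 siRNA 3 array.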

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

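The tests of the interferon and siRNA patterns below were chosen after those results had been seen, and the regroupings of the arrays were planned before their results were seen. The result singled out is the interferon response list, whose response differed between the lines by a mean of 1.74 on the log2 scale in a direct test (A673 minus SK-N-MC, camera adjusted p = 2.24e-32, 0.751 with an estimated correlation). Most members were dim in the A673 control array (list median 2.62, that of the whole array), so the 1.74 may partly reflect this starting level. The lines also differed in the STEAP1 level left by siRNA 2 and siRNA 3. It was 30.8% and 32.1% of control in A673, and 12.7% and 18.7% in SK-N-MC. Whether this difference plays a part was not tested.

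Interferon genes were lower in both SK-N-MC siRNA arrays than in the single control array. Immune cells in the control culture are argued against by leukocyte markers, whose median control minus siRNA difference was -0.13 (upper quartile 0.04), with LYZ at 2.15, PTPRC at 2.22 and TYROBP at 10.1 intensity units in the control array. Several explanations stay open. A high interferon state of the control array alone cannot be told apart from a response to silencing. The median difference over the list between the siRNA arrays (siRNA 2 minus siRNA 3) was -1.04 in SK-N-MC, with 42 of 43 members lower with siRNA 2. Most of 10000 random lists lay between -0.104 and 0.107. A state of the control array alone would not give this difference. Camera with an estimated correlation (adjusted p = 0.813) tested the siRNA difference over both lines, with a median of -0.025 in A673, and so does not test SK-N-MC alone. The explanation stays open because the SK-N-MC siRNA arrays are single arrays and the list moves as a unit. An effect of lower STEAP1 alike in both lines also stays open, for the same reason. Of the interferon list, 15 members lay at a log2 of 4 or more in the A673 control array. Their median response was -0.16 in A673 and -1.54 in SK-N-MC, each against 1 control array. All 15 were lower in A673, and 13 of them had a lower response in SK-N-MC than in A673. Different induction of interferon genes by the control siRNA and the STEAP1 siRNAs may explain the order of the 3 SK-N-MC arrays (list median 4.50 with siRNA 3, between 5.48 and 2.98), and it cannot be told apart from a SK-N-MC response to STEAP1 without untransfected cells and further control arrays. The control siRNA is not named and may differ between the lines, which leaves the 1.74 open to it as well.

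Arrays of siRNA 2 and siRNA 3 differed alike in both lines among genes with a mean log2 of at least 6 (correlation 0.299), and less so with a limit of 4 (0.193) or over all genes (0.0663). Interferon genes as the source are argued against at the limit of 4, where 18 of them were in the set and the correlation without them and STEAP1 was 0.196. At the limit of 6 only 3 were in the set. Of the 6 ways to match the 3 arrays of one line with those of the other, the matching by label gave the highest correlation over genes and arrays, 0.230 at the limit of 6, and the next gave 0.0814. Over all genes these values were 0.0645 and 0.0356. The matching by label also pairs the control arrays, so a response shared by both lines would raise its value too. With the control arrays paired and the siRNAs swapped, the value was -0.0830 at the limit of 6. With 6 matchings no share under 0.05 is possible. Effects that depend on the siRNA sequence beyond STEAP1 are a candidate explanation, and the sequences were not analysed here. Joint handling of same-numbered arrays would give the same value, 0.230, and cannot be told apart from it, because the labels give no batch.

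Other groupings of the arrays were counted for 2 comparisons. Between the lines, 1 of the 10 splits of the 6 arrays into 3 and 3, the real one, gave as many as 4575 calls, and the highest of the other splits gave 0. For silencing across lines, 6 of the 9 choices of 1 array per line as the control gave at least the real 852 genes at an unadjusted p under 0.05, and the highest other choice gave 1242. Both sets of groupings are too few for a share under 0.05.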

How the results depend on the processing

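Alternatives with a milder filter (mean log2 of 4) or without the interferon list and STEAP1 were chosen after the data had been seen, and the rest were planned. Across lines, the count of called genes was 0 under every alternative except 1 gene lower (XAF1) without the A673 control array. There SK-N-MC alone gave the silencing response. STEAP1 kept its direction across lines and missed the threshold under all 15 alternatives (-2.70 to -1.67, adjusted p 0.0511 to 1.00). In SK-N-MC it passed with an intensity trend (0.0166), a second quantile normalization (0.0368), the filter at 4 (0.0402), and without siRNA 2 (0.0367) or siRNA 3 (0.00152), adjusted p 0.00152 to 1.00 over its alternatives. There, 5 genes were lower with an intensity trend, 4 after a second quantile normalization and 0 with the filter at 6, which leaves XAF1 untested; leaving out single arrays gave 0 to 60 lower and 0 to 1 higher genes there, and 0 to 26 higher in the difference of the responses, the highest counts without the SK-N-MC siRNA 3 array, where only the A673 siRNA arrays give the spread. With an estimated correlation 0 lists were called, and the interferon list (-0.92 across lines, -1.79 in SK-N-MC, 1.74 in their difference) lost its calls; the last also did at the filter of 6 (1.13, adjusted p = 0.120, range over alternatives 4.42e-67 to 0.751). With siRNA 2 alone 2 lists were called, and leaving out single arrays gave 0 to 3 lists and an interferon mean of -1.79 to -0.055 across lines. Between lines 648 genes were higher and 521 lower with the filter at 6, where fewer genes were tested, 1355 were lower at 4, and 1330 to 2120 were lower with single arrays left out. At least 2-fold in all 4 siRNA arrays 0 genes were higher and 1 lower; with the filter at 6 these counts were 0 and 0, and at 4 none was higher (0). Between-line correlations were 0.282 and 0.0789 for same and different siRNAs at the filter of 6, and 0.172 for the same siRNA at 4. The signs of near-zero values changed: STEAP2 (0.012 after a second quantile normalization, 0.18 with siRNA 3 alone, -0.097 to 0.11 with single arrays left out), STEAP4 (0.025 with siRNA 3 alone, -0.14 to 0.047), EWSR1 (-0.0068 with median centring, -0.029 with siRNA 2 alone, -0.036 to 0.047) and ACTB (0.048 with siRNA 2 alone, -0.14 to 0.092). STEAP3 also changed sign, because its values were opposite in the lines: -0.50 without the SK-N-MC control array and 0.25 without the A673 control array. Between siRNAs, single arrays left out gave -1.46 to 0.26 for the interferon list, -0.060 to 0.27 for the unfolded protein list, -3.70 to 0.45 for CXCL10 and -3.50 to 0.39 for MX1. Each siRNA has 1 array per line, so without one of them that siRNA is measured in the other line alone. Between lines the immediate early list stood at -0.080 with the filter at 6, and the cause was not tested. The siRNA number as a block gave 0 genes across lines, and 2548 higher and 2172 lower between lines beside 2479 and 2096 without it; the numbers mark the siRNA, and there are only 2 pairs. There were 1487 further values, for 121 pairs of a named gene and a comparison. Of the 1487 values, 1442 kept their direction and side of the threshold, 25 newly passed it, 2 lost it and 18 changed sign. The response of a line could not be fitted without its only control array. Dim genes limit the comparisons, since 7413 of 18417 genes have a mean log2 of at least 4.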
